A study of Homo sapiens with 17 samples.

How the data were processed

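Chromatin loops marked by H3K27ac, a histone mark of active promoters and enhancers, were mapped by HiChIP in 17 human cell cultures, with 1 deposited loop list per culture. HiChIP joins chromatin ends that lie close together in the nucleus and enriches the joined fragments with an antibody, so that each listed loop is a pair of genome bins held together near the mark. The cultures were 11 epithelial types (airway, bladder, colon, esophageal, mammary, ovarian, pancreas, prostate, renal, thyroid and uterine), astrocytes, the B-lymphoblastoid line GM12878, keratinocytes, melanocytes, and the melanoma lines COLO 829 and WM-266-4. The keratinocytes were kept in 1.2 mM calcium for 6 days and the melanoma lines in the solvent DMSO for 24 hours, per the labels.

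Each deposited list gave pairs of 5 kb bins on the same chromosome, 20 kb to 2000 kb apart, with a column headed as a count. The genome build was hg19, and STAR, HiC-Pro and limma were named without roles or versions, per the submitters' processing notes. The loop caller, its threshold and the sequencing depth were not given in the sources used here. No significance value came with a loop, so the lists hold only what passed the authors' threshold. A bin pair outside a list may have had contacts below it, or none.

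The deposited value column was not a single count. Of 1022056 autosomal values with 4 digits, 0 had the digit 0 as the third digit, which separate numbers written one after the other would give and a single number would not. In WM-266-4, 1228 loops read 99 and 0 read 95, while 782 read 88 and 0 read 85. The values were therefore read as the counts of the replicates in which a loop was listed, joined as digits. Values of 4 digits were split in the middle, and longer ones at the place nearest to the sample's usual ratio of the first to the second count. Pancreas and uterine lists were read as 3 replicates, because 23.3% and 70.0% of their values with at least 6 digits had at least 7, against at most 0.515% in the 15 lists read as 2. In these lists a value of 6 digits was read as 3 counts where all were at least 10 and none was below the middle one, which held for 165 of 662 in pancreas and 1902 of 2007 in uterine cells. The reading was unclear for 27037 loops, between 0.210% and 2.73% of a sample. A loop's contacts were the sum over its replicates. This reading is an inference from the digits, and no source used here states it.

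Because the column was not a count and no values per replicate existed for loops listed in 1 replicate, the count-model test planned for contact counts was not used. Contacts were summed in 100 kb windows, each loop counting once in the window of each anchor, and scaled to CPM by the sample's total over all windows. A loop with anchors in different windows entered each of them. Neighbouring windows therefore share contacts, are not independent, and do not support each other where named together. Single loops were scaled to CPM by the sample's listed contacts. Windows with at least 5 CPM in at least 5 samples were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale and understate changes of low windows. Each sample is a different cell type with its replicates pooled, so the spread behind every p-value is that between cell types, and nothing in the labels says how many donors or cultures stand behind a list.

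The epithelial comparison set 11 epithelial samples against 5 non-epithelial ones (astrocytes, GM12878, melanocytes and both melanoma lines). Keratinocytes were left out of its main form because their label does not place them. Colon, esophageal, ovarian, pancreas, renal and thyroid cells came from 1 supplier and were grown in 1 medium, and the other 5 epithelial samples came from 3 other suppliers, so these 6 were also compared with those 5. Loop sharing was measured with the Jaccard index, the loops in both lists over the loops in either. Differences in mean Jaccard index and in median loop length were tested by exact two-sided permutation over all splits of the samples. Equal list lengths took the 56767 loops with most contacts from each sample. The melanoma lines were compared with the single melanocyte sample without a test, over windows with at least 20 contacts summed over the 3 samples. Correlations of replicates with other cell types left out the pancreas and uterine replicates, since their values were read as 3 replicates. Binomial intervals are exact Clopper-Pearson at 95% and cover counting error only.

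The windows named were the 8 with the largest fold in each direction among those past the threshold with the same direction in at least 9 of 11 epithelial samples against the non-epithelial median. In the supplier comparison all 6 samples had to lie on the same side of the median of the other 5, a rule set after the lists had been opened. In the melanoma comparison the rule took the 8 with the largest fold in each direction, and for single cell types and loop classes the text gives the leading windows and loops. These rules were written for genes and applied to windows. The width of 100 kb and the window filter were chosen after the lists had been opened.

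No hg19 gene annotation was used here. The reference table given was of GRCh38, so loops could not be assigned to genes, no gene is named, and the gene lists fixed before the data were examined were not analysed here. The composition scaling first chosen for counts (a trimmed mean) was replaced by the sample's total. Only autosomes were analysed. Alternatives covered scaling, filter, pseudocount, window width, list length, replicate reading, the definition of a shared loop and the samples used.

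The window comparison, the sharing test and the replicate correlation were tested on simulated data. Smaller folds were mostly missed in a first simulation, and folds placed in 1 group only shifted the totals and raised the false calls. The simulation described here used larger folds, split over both groups so that totals stayed level. With 200 changed windows, limma recovered 11.9% of 4-fold, 94.0% of 16-fold and 100% of 64-fold changes in the epithelial comparison of 13683 simulated windows, with 4 false calls among 141. In the supplier comparison of 11880 simulated windows it recovered 61.2%, 100% and 100%, with 13 false calls among 187. These simulated samples were independent, had 1 spread for all windows and passed no listing threshold, unlike the real lists. The rates therefore need not hold for the real windows. The permutation test of sharing passed the threshold in 0 of 20 simulations without a group core of loops and in 20 of 20 with one. Its simulated lists were of equal length and unrelated apart from that core, unlike the real lists, so effects of list length were not simulated. Replicates simulated from 1 profile correlated at 0.918 between samples and 0.917 within them, and unrelated profiles at −0.00348. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.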

Results

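The 17 lists held 3448492 autosomal loops and 114638487 contacts in all. Airway cells had the shortest list with 56767 loops and the melanoma line WM-266-4 the longest with 427286, a 7.53-fold range around a median of 178331. Melanocytes had 81492 loops, mammary cells 108618, GM12878 164877, keratinocytes 168211, astrocytes 192601, renal cells 220928, COLO 829 239446 and uterine cells 415548. Listed contacts ran from 1570757 in airway cells to 18886858 in WM-266-4. These totals cover listed loops only and are not library depths, which are unknown.

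Replicates of a cell type agreed to very different degrees. WM-266-4 had 54.0% of its loops listed for at least 2 replicates (95% interval 53.8% to 54.2%), esophageal cells 43.3% and COLO 829 42.6%. Renal cells had 11.6% (11.5% to 11.7%), astrocytes 12.1% and melanocytes 13.5% (13.3% to 13.8%), against a median of 33.3% over the 17 samples. Across loops with 4-digit values, the Pearson correlation between log2 counts of the replicates was 0.898 in GM12878, 0.894 in ovarian cells and 0.893 in esophageal cells. It was 0.620 in melanocytes and 0.505 in renal cells. Loops are not independent replicates, and these coefficients describe the lists.

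**Figure D1:**
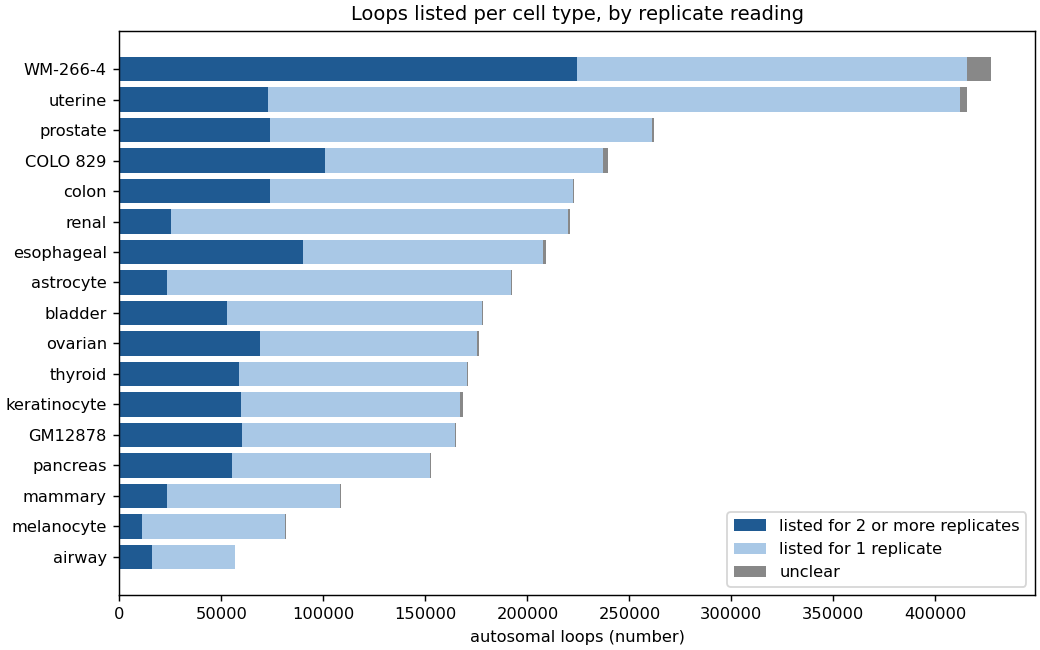
Number of autosomal loops per cell type, as bars split into loops listed for 2 or more replicates, loops listed for 1 replicate and loops of unclear reading. WM-266-4 has the longest list at 427286 loops and airway cells the shortest at 56767, and renal cells, astrocytes and melanocytes have the smallest replicated shares, at 11.6%, 12.1% and 13.5%.

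The renal replicates resembled different cell types. Only shared loops with 4-digit values in the list whose replicates were taken could be used. The renal list had 24518 loops with such values among 220928. Counts of the first renal replicate correlated at 0.793 with colon, 0.791 with thyroid and 0.774 with ovarian contacts across these loops. Counts of the second correlated at 0.487, 0.474 and 0.483. The second replicate correlated more than the first with astrocytes (0.594 against 0.449, higher on 21 of 22 autosomes) and with melanocytes (0.567 against 0.398, higher on 22 of 22). The melanocyte replicates also differed. The first correlated at 0.630 with renal cells and 0.596 with astrocytes but at 0.376 with COLO 829 and 0.322 with WM-266-4, while the second gave 0.476, 0.449, 0.483 and 0.430. In GM12878 and esophageal cells the difference between the replicates varied by 0.0194 and 0.0132 over the compared cell types, against 0.485 in renal cells and 0.262 in melanocytes.

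**Figure D2:**
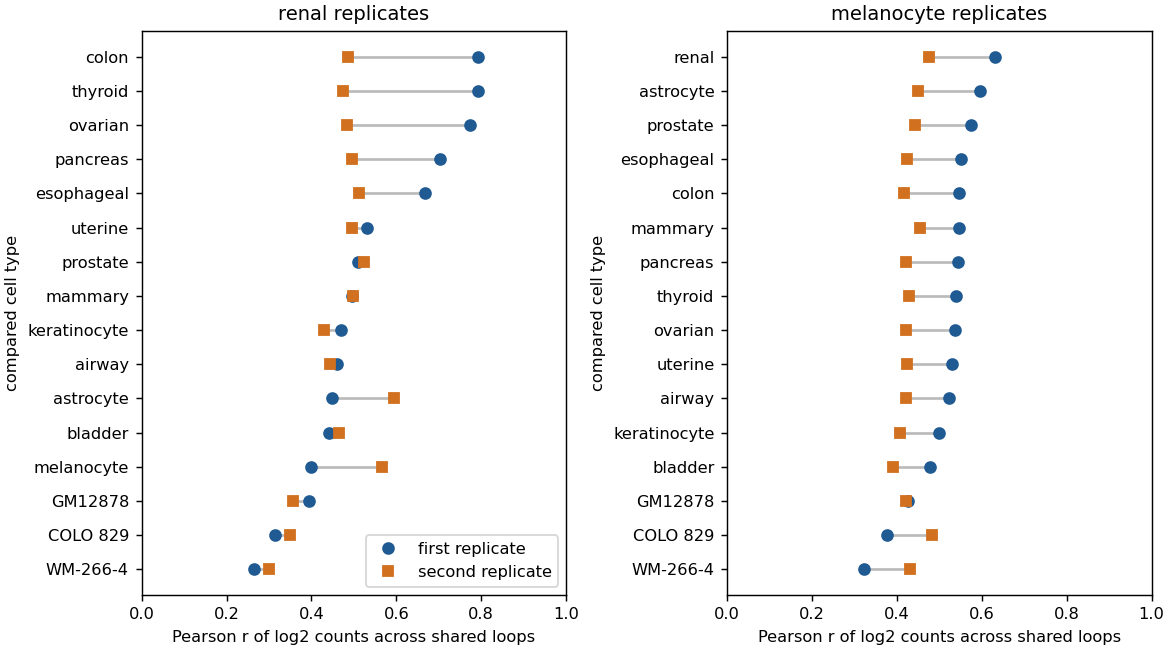
Pearson correlation of log2 replicate counts with log2 contacts of each other cell type across shared loops, for the first (circles) and second (squares) replicate of renal cells and of melanocytes. The first renal replicate lies at 0.793 with colon and the second at 0.487, and with astrocytes the order turns (0.449 and 0.594).

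The comparison of epithelial with non-epithelial cells asked which regions carried H3K27ac loops in epithelia of many organs and not in the other cell types. The highest window by fold was chr15:92,400,001–92,500,000 (hg19), at 576 ± 384 CPM (scaled contacts) in epithelial cells (SD, n = 11) and 11.5 ± 25.8 in non-epithelial cells (SD, n = 5), where only astrocytes had any. At chr8:128,400,001–128,500,000 epithelial cells had 941 ± 565 CPM, from 221 in renal to 1960 in mammary cells, and the non-epithelial samples 10.2 ± 13.7. Keratinocytes, which were outside the test, had 2442 there. At chr12:52,900,001–53,000,000 the values were 532 ± 293 and 14.0 ± 27.4, with 1240 in keratinocytes, and at chr8:142,200,001–142,300,000 all 5 non-epithelial samples were listed at 0 against 132 ± 78.5. The opposite pattern was seen at chr10:11,200,001–11,300,000, where all 11 epithelial samples and keratinocytes were listed at 0 and GM12878 had 587, melanocytes 192, WM-266-4 131, COLO 829 46.2 and astrocytes 7.38.

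By limma, 2001 of 14228 windows differed at an adjusted p under 0.05, 1299 higher and 702 lower in epithelial cells. The log2 difference was 7.73 ± 0.79 (SE) with an adjusted p of 2.38e-06 at the chromosome 15 window and 7.50 ± 0.73 with 1.83e-06 at chr8:128,400,001–128,500,000. Adjacent windows on chromosome 4, which can hold the same loops, gave 7.48 ± 0.69 at chr4:11,600,001–11,700,000 and 6.75 ± 0.66 at chr4:11,500,001–11,600,000. On chromosome 8, chr8:120,100,001–120,200,000 (7.55 ± 0.64) and chr8:10,500,001–10,600,000 (7.11 ± 0.79) were also higher. All 8 named windows were higher in all 11 epithelial samples than the non-epithelial median.

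Windows lower in epithelial cells included chr4:109,000,001–109,100,000, at 0.252 ± 0.632 CPM against 198 ± 186 (log2 −6.66 ± 0.72, limma adjusted p = 5.27e-06). COLO 829 (346), WM-266-4 (443) and melanocytes (116) led there. At chr5:88,100,001–88,200,000 GM12878 (492) and WM-266-4 (611) stood highest, and its neighbour chr5:88,000,001–88,100,000 also fell (log2 −5.85 ± 0.69). The window chr15:48,300,001–48,400,000 was melanocytic, with 253 in melanocytes, 330 in COLO 829 and 316 in WM-266-4 against 6.36 in astrocytes and 6.09 in GM12878. At chr20:47,300,001–47,400,000 and chr1:25,300,001–25,400,000 GM12878 was highest, at 460 and 485. At chr2:145,200,001–145,300,000 the epithelial samples were not uniform, since renal cells had 123 CPM and pancreas cells 43.7 while 6 others were listed at 0.

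Of the non-epithelial samples left out, the melanoma lines (2 of the 5) lowered this count most. Without both lines 772 windows differed (802 when the same 14228 windows were kept, a setting chosen after seeing the data), and without COLO 829 or WM-266-4 alone 1196 and 1117. With median-of-ratios scaling the calls were 1070 higher and 925 lower, or 53.6% higher in place of 64.9%, and the median log2 difference of all windows moved from 0.18 to −0.05. Without the contact filter 24849 windows were tested, with 1117 higher and 1141 lower (49.5% higher) and a median of −0.07, so the excess of higher windows depended on both choices.

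**Figure D3:**
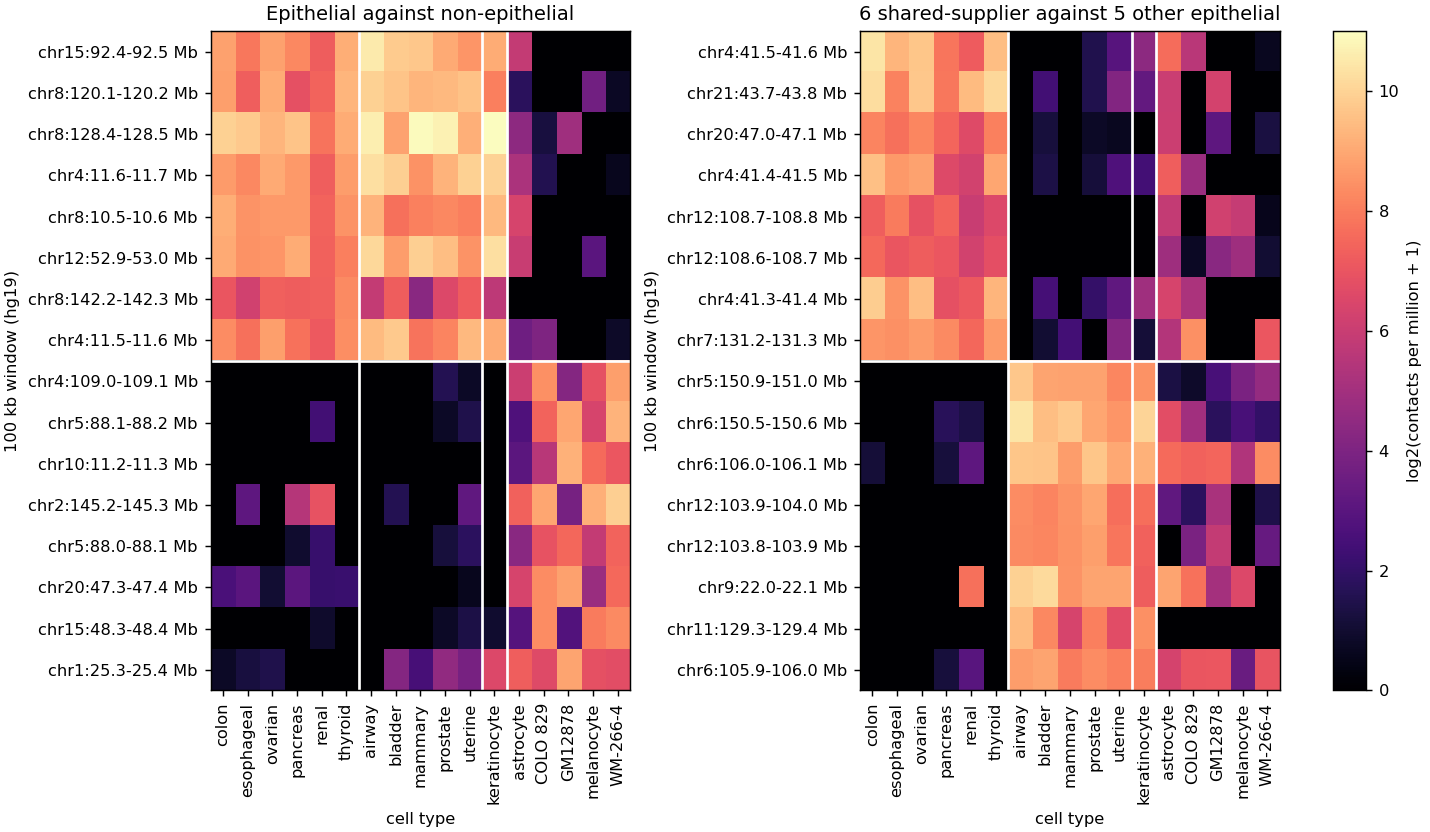
Contacts (CPM) as log2(value + 1) in colour for each named 100 kb window (rows) and cell type (columns), for the epithelial comparison (left) and the supplier comparison (right). Vertical lines part the 6 shared-supplier epithelial samples, the 5 other epithelial samples, keratinocytes and the 5 non-epithelial samples, and the horizontal line parts windows higher and lower in the first group.

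Epithelial lists shared more loops with each other than with the other cell types. The mean Jaccard index was 0.225 among the 11 epithelial samples and 0.120 between them and the 5 non-epithelial samples, a difference of 0.106 (exact permutation test, p = 0.000458, 4368 splits). The single other split with as large a value, 0.109, exchanged airway cells, which have the shortest list, for astrocytes. With equal list lengths the difference was 0.161, and no other split reached it (p = 0.000229, the smallest these splits can give). GM12878 stood farthest apart, with 0.126 to its nearest list, that of ovarian cells. Set against the same 5 non-epithelial samples, the difference was 0.196 for the 6 shared-supplier samples (exact p = 0.00216) and 0.118 for the other 5 (exact p = 0.00397), each the smallest p its splits can give. The samples of these comparisons came from several suppliers. Within 1 supplier, looked up after seeing the data, the index was 0.221 between airway and bladder cells and 0.0761 between these and the melanoma lines. Within another it was 0.241 between mammary and prostate cells and 0.162 between these and astrocytes. No test was run on these few samples, and the shared supplier gave no non-epithelial sample.

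Pairs of cell types from different organs were closest within the shared supplier. Ovarian and thyroid lists had a Jaccard index of 0.414, colon and ovarian 0.396, esophageal and pancreas 0.391, and colon and thyroid 0.390. Renal cells lay lower, at 0.254 with ovarian and 0.251 with colon cells. Among the other epithelial samples, bladder and prostate reached 0.286, prostate and uterine 0.278 and airway and mammary 0.251. Keratinocytes were nearest to prostate (0.261) and mammary cells (0.238). Astrocytes (0.213) and melanocytes (0.157) were both nearest to renal cells, whose replicates differed as described.

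**Figure D4:**
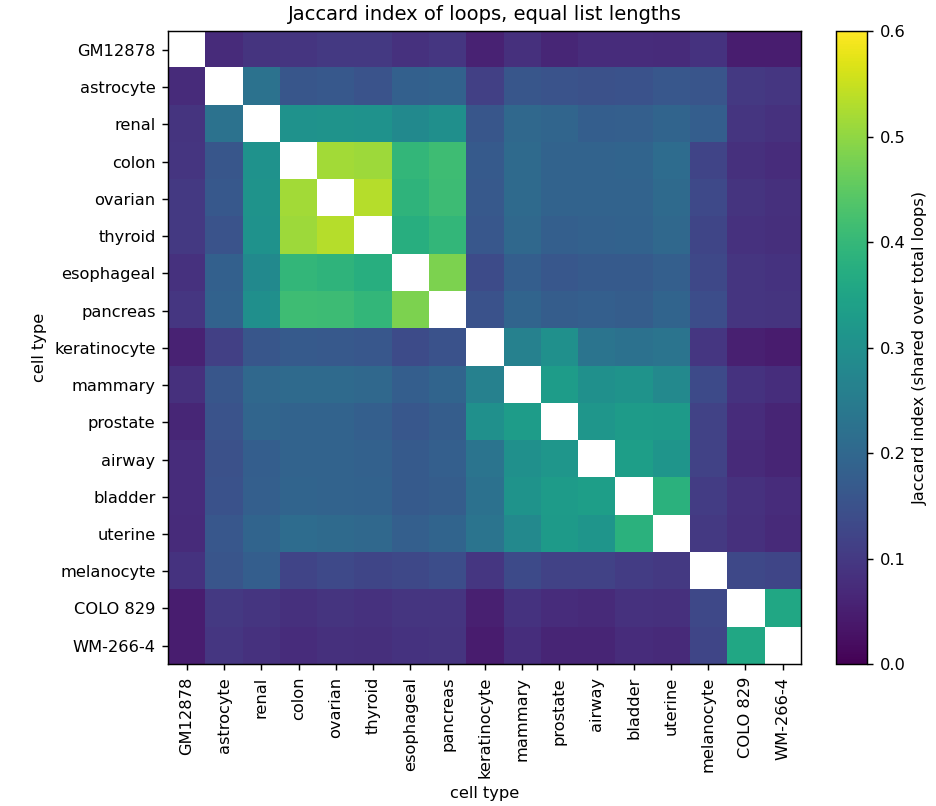
Jaccard index of loop lists for each pair of the 17 cell types, with 56767 loops taken from each. Colon, ovarian and thyroid cells form the brightest block, with ovarian and thyroid at 0.533, and the other epithelial samples lie with keratinocytes in a separate block.

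Many regions had contacts in the 6 shared-supplier epithelial samples or in the other 5, and few or none in the other set. At chr5:150,900,001–151,000,000 all 6 shared-supplier samples were listed at 0, and the other 5 had 514 ± 205 CPM (SD, n = 5), with 357 in keratinocytes. The same held at chr12:103,900,001–104,000,000 (341 ± 111), at its neighbour chr12:103,800,001–103,900,000 (327 ± 77.0) and at chr11:129,300,001–129,400,000 (291 ± 244), where keratinocytes had 347 and all 5 non-epithelial samples were listed at 0. At chr6:150,500,001–150,600,000 the values were 0.660 ± 1.04 and 770 ± 391 (log2 −8.92 ± 0.52, limma adjusted p = 6.20e-08), with 1037 in keratinocytes. At chr9:22,000,001–22,100,000, 5 of the 6 shared-supplier samples were listed at 0 and renal cells had 208, against 693 ± 349 in the other epithelial samples. The shared-supplier samples were higher than the other 5 at chr4:41,500,001–41,600,000 (653 ± 445 against 1.73 ± 2.92, log2 8.09 ± 0.67, limma adjusted p = 1.06e-06), along with the adjacent windows from chr4:41,300,001 to 41,500,000. At the first of these astrocytes, from another supplier, had 196, above the 144 of renal cells. COLO 829 had 47.4 there, WM-266-4 0.605, and GM12878 and melanocytes 0. The shared-supplier samples were also higher than the other 5 at chr21:43,700,001–43,800,000 (729 ± 407 against 4.54 ± 6.95) and at chr20:47,000,001–47,100,000 (225 ± 77.6 against 0.519 ± 0.547). At chr12:108,600,001–108,700,000 and chr12:108,700,001–108,800,000 the other 5 and keratinocytes were all listed at 0. At the latter, GM12878 had 74.0, melanocytes 58.9 and astrocytes 56.5, near the 62.9 of renal cells, while COLO 829 had 0 and WM-266-4 0.509. Contacts at such windows were thus not particular to the shared-supplier samples.

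Supplier and medium divided the epithelial samples. The 6 shared-supplier lists had a mean Jaccard index of 0.326 among themselves and 0.175 with the other 5, a difference of 0.151 (exact permutation test, p = 0.00216, the smallest that 462 splits can give). The other 5 had 0.225 among themselves, and this did not pass the test against 0.175 at full list length (exact p = 0.0736) but passed with equal lengths, 0.323 against 0.189 (exact p = 0.0152). By limma, 5401 of 12217 windows differed between the 6 and the 5, 2729 higher and 2672 lower in the shared-supplier samples. Without the contact filter, a setting chosen for this comparison after seeing the data, 2495 were higher and 3282 lower. Supplier, medium and organ change together here, because no organ came from both supplier groups.

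Most loops were listed in few cell types. Of 1379833 distinct loops, 54.6% were in 1 sample only and 2633 (0.191%) were in all 17. The loop in all 17 with the highest median, 163 CPM, joined chr17:57,860,001–57,865,000 to chr17:57,905,001–57,910,000 over 45 kb. The share of a sample's loops found in no other sample was 42.7% in WM-266-4 (95% interval 42.6% to 42.9%), 42.5% in GM12878, 30.7% in uterine cells, 7.04% in mammary cells and 2.52% in airway cells, with a median of 14.5%. This order moved with list length. With equal list lengths the share was 57.7% in GM12878, 32.5% in melanocytes (12.6% in the full lists), 32.0% in WM-266-4, 16.05% in airway cells and 12.6% in uterine cells. In the full lists, loops of 1 cell type were less often listed for at least 2 replicates than shared loops in all 17 samples. The median share was 3.39% of unique and 38.0% of shared loops. With equal list lengths the medians were 76.4% and 84.2%, and the share was lower for unique loops in 16 of 17 samples. In the full lists it was 0.209% of the unique loops and 14.5% of the shared loops of renal cells, and 0.753% and 15.4% in melanocytes. In GM12878 it was 27.8% and 42.8%.

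A loop counted as present only where the same pair of 5 kb bins was listed, so a nearby pair may be listed elsewhere. With anchors allowed to differ by 1 bin, the median share of loops in no other sample fell from 14.5% to 4.53%. Under the exact definition, each class was described by loops present in every member and in no other list. The 3 melanocytic samples had 4276 such loops, led by the loop from chr17:59,325,001–59,330,000 to chr17:59,395,001–59,400,000 with a median of 152 CPM. GM12878 was led by chr6:295,001–300,000 to chr6:315,001–320,000 (140), chr8:11,350,001–11,355,000 to chr8:11,390,001–11,395,000 (120) and chr11:111,235,001–111,240,000 to chr11:111,285,001–111,290,000 (101). All 11 epithelial samples shared 12202 loops, and 103 of these were absent from every other list, that of keratinocytes included. They were led by chr2:224,660,001–224,665,000 to chr2:224,680,001–224,685,000 (28.6). A loop of this class had to be in 11 lists at once, the short airway list among them. The count therefore does not compare with those of smaller classes. The 6 shared-supplier samples had 1854 loops in no other list, led by chr17:70,400,001–70,405,000 to chr17:70,420,001–70,425,000 (57.3). The 100 kb window holding this leading loop also had contacts in lists outside the class. The other 5 epithelial samples and keratinocytes, a class set after the data had been seen, had 1574, led by chr5:52,555,001–52,560,000 to chr5:52,615,001–52,620,000 (68.4).

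Single cell types also had leading windows against the median of the others. GM12878 had 1209 CPM at chr6:300,001–400,000 and 916 at chr9:37,300,001–37,400,000, where the median of the others was 0 and the next highest were 63.9 in COLO 829 and 8.66 in uterine cells. Melanocytes had 942 at chr10:14,400,001–14,500,000, where astrocytes followed with 365. Astrocytes led at chr13:36,700,001–36,800,000 (481, next renal cells at 57.2), uterine cells at chr4:168,400,001–168,500,000 (398, next bladder cells at 27.8) and bladder cells at chr10:8,700,001–8,800,000 (378, next prostate cells at 73.2). The leading window of keratinocytes, chr10:108,100,001–108,200,000, had 410, followed by prostate cells with 324. Each of these values is from 1 list, and no test was run.

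Loop length did not separate epithelial from other cells. Median lengths were 102 ± 11.3 kb in epithelial samples (SD, n = 11) and 104 ± 8.94 kb in non-epithelial samples (SD, n = 5), a difference of −1.73 kb (exact permutation test, two-sided p = 0.805). In lists of equal length made only of loops listed for at least 2 replicates, a setting chosen after seeing the data, the difference was −18.9 kb (exact p = 0.049). It rested on melanocytes, whose median was 115 kb in a list that set the common length of 10982 loops and so was not shortened. Without melanocytes the difference was −5.91 kb (exact p = 0.290), and without astrocytes −18.4 kb (exact p = 0.138).

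The melanoma lines were compared with melanocytes, the normal cells of that lineage, to see which regions differed in both. The melanocyte list pools replicates that differed as described, with 13.5% of its loops listed for at least 2, which limits every difference from it. COLO 829 and WM-266-4 had 781 windows with at least 100 CPM in each line and at least 2-fold more than melanocytes. The leading ones were chr8:89,000,001–89,100,000 (780 in COLO 829 and 441 in WM-266-4), chr7:77,800,001–77,900,000 (555 and 555), its neighbour chr7:77,700,001–77,800,000 (498 and 525) and chr2:144,300,001–144,400,000 (478 and 471). Melanocytes were listed at 0 in all 4, as was the median of the other 14 samples. Scaled to the melanocyte total, the lower of the rates of the lines would be 1331 contacts at the chromosome 8 window. This assumes listing in proportion to contacts, whereas each loop had to pass an unknown threshold, so the listed 0 does not show absence. Other leading windows were chr10:29,600,001–29,700,000 (476 and 377), chr12:29,100,001–29,200,000 (590 and 228), chr2:67,100,001–67,200,000 (428 and 313) and chr3:59,000,001–59,100,000 (373 and 316), with melanocytes again listed at 0.

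Windows with more contacts in melanocytes included chr10:14,300,001–14,400,000 (500 CPM, against 0 and 0.573), chr16:86,600,001–86,700,000 (443, against 0 and 0) and chr21:39,700,001–39,800,000 (420, against 0 and 0). However, 7 of the 8 leading windows of this kind had no melanocyte loop listed for at least 2 replicates, compared with 14.5% of the 1319 melanocyte-higher windows with at least 100 CPM. Over all 19059 windows compared, 5043 were at least 2-fold higher and 4108 at least 2-fold lower in both lines, with 436 going opposite ways. The balance depended on the loops used. It was 2717 higher and 4379 lower with equal list lengths, and 7305 higher and 2480 lower with loops listed for at least 2 replicates. The lines themselves differed by at least 2-fold in 9681 windows. With 1 melanocyte sample no test was run.

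COLO 829 and WM-266-4 shared 159200 loops, a Jaccard index of 0.314. Melanocytes, whose nearest list was that of renal cells, had an index of 0.112 with COLO 829 and 0.0833 with WM-266-4. With equal list lengths these became 0.131 and 0.125, and melanocytes were then the nearest list to each line after the other line.

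The lines also placed their contacts on different chromosomes from the other 15 samples. Chromosome 7 held 9.60% of COLO 829 and 8.95% of WM-266-4 contacts, against a median of 4.47% and a highest value of 6.28% in the others. Chromosome 2 (10.8% and 10.1%, others at most 8.69%), chromosome 8 (8.17% and 6.68%, others at most 6.63%) and chromosome 13 (3.78% and 3.75%, others at most 3.15%) were also above the range in both lines, and chromosomes 9 and 16 below it. DNA copy number was not measured here, so these shares do not separate copy number from regulation. COLO 829 lay outside the range of the others on 14 of 22 autosomes and WM-266-4 on 8. With equal list lengths these were 12 and 8, and COLO 829 was then inside the range on chromosome 9 (2.56%, lowest other 2.51%) and on chromosome 15. On chromosome 12 the lines parted, with 8.21% in COLO 829 above the range and 4.67% in WM-266-4 below it.

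**Figure D5:**
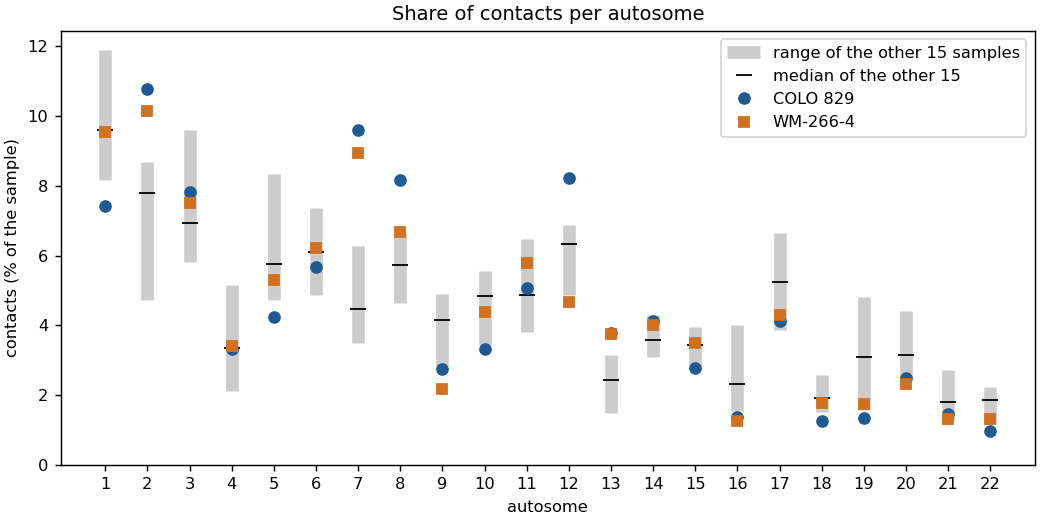
Share of each sample's contacts per autosome in percent, for COLO 829 (circles) and WM-266-4 (squares), with the range (bars) and median (ticks) of the other 15 samples. Both lines lie above the range on chromosome 7, at 9.60% and 8.95%.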

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

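All tests in this part were chosen after the result was seen, except that of chromosome 7 copies, which was set once the shares per chromosome, but not its own medians, had been seen. Equal list lengths in the supplier comparison were a setting fixed earlier, but their use to test a cause was chosen here.

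Renal cells stood apart from the other shared-supplier samples, with 11.6% of loops listed for at least 2 replicates and a correlation of 0.505 between replicate counts, each below the other 5 samples by more than Dixon's critical value (2 of 15 sets of values tested, where chance gives about 1 in 20). Lower depth of the second replicate is argued against, because that replicate correlated more than the first with melanocytes, by 0.181 ± 0.0926 (mean and SD over 22 autosomes). Across loops with 4-digit values the median count of the second replicate was 23, against 20 in the first. These medians cover only loops listed in both replicates, and the 194626 loops listed for 1 replicate could not be assigned to either. Relative depth can therefore not be read from them. Astrocytes and melanocytes had, with renal cells, the lowest replicated shares (12.1% and 13.5%), so low library quality as such was not told apart. A mixed or mislabelled replicate is a candidate explanation, since the second replicate correlated most with astrocytes (0.594), above its highest value with a shared-supplier list (0.513, esophageal). Which cells these were cannot be read from the lists. No biological explanation was tested, because both replicates carry 1 label.

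The 6 shared-supplier samples and the other 5 epithelial samples differed in 5401 windows by limma, and 2001 windows differed between epithelial and non-epithelial cells. The counts are not comparable in size, since 61.2% of simulated 4-fold changes were recovered in the supplier comparison and 11.9% in the epithelial one. Chance is argued against for both counts but not excluded. Only 100 splits each were counted, of 462 possible in the supplier and 4368 in the epithelial comparison. The real split was the only 1 of 100 to reach 5401, and the highest other gave 2311. In the epithelial comparison it was also the only 1 of 100, and the highest other gave 25.

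Replicates of the 10 shared-supplier pairs correlated between organs at a median of 0.617 (0.545 to 0.809), below 0.800 within a cell type. The median over 95 other pairs was 0.425, but these include non-epithelial samples and pairs across the supplier groups. Pairs among airway, bladder, mammary and prostate cells, from other suppliers, ran from 0.573 (bladder and mammary) to 0.629 (mammary and prostate). By this measure they were close to the shared-supplier median. The closest shared-supplier pair, ovarian and thyroid, reached 0.809 between the organs and 0.841 within them. List length is argued against as the whole cause, because the difference in mean Jaccard index was 0.206 with equal list lengths and 0.151 at full length. Counts of 1 replicate copied under both of these labels are argued against, because at most 5.95% of loops had equal counts in a pair of replicates across them. An exchange of cells or libraries between the labels stays open, because thyroid replicates correlated with each other at 0.809, no more than with ovarian replicates, and more than between the labels on only 11 of 22 autosomes, against 0.873 and 22 of 22 for ovarian replicates. A batch of supplier, medium or handling and a real likeness of these epithelia cannot be told apart, because 0 organs were seen from both supplier groups, and cells of common origin in several cultures were not tested.

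Both melanoma lines listed a larger share of contacts on chromosome 7 than any other sample. Longer lists are argued against, because with equal list lengths the lower share of the lines was 9.42%, above the highest of the others (6.23%). Extra copies of chromosome 7 may account for it. Over its 302 windows with contacts in all 17 samples, the median log2 difference from the median of the other 15 was 1.03 in COLO 829 and 0.83 in WM-266-4. Each line's median over all 5845 such windows had been subtracted. Quartiles on chromosome 7 were −0.25 and 2.16 in COLO 829 and −0.39 and 1.84 in WM-266-4, so regulation of single regions stays open, and no copy number was measured here. Chromosome 7 was not alone, since chromosome 13 gave medians of 0.85 and 0.65 by the same measure.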

How the results depend on the processing

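Settings based on replicate reading, window width, median-of-ratios scaling or the renal sample, the upper part of the lists for loops of 1 cell type, samples left out with the same windows kept or from replicated lists of equal length, and all but 2 settings of the supplier comparison (equal list lengths, anchors within 1 bin), were chosen after seeing the data. The higher sharing among epithelial lists and among shared-supplier lists kept its direction and passed the exact test in all 15 and 12 alternatives, with differences from 0.0999 to 0.203 and from 0.112 to 0.248. The supplier windows numbered 3866 to 5777 over 19 alternatives, each within 1.5 times of 5401.

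The count of epithelial windows, 2001, was within 1.5 times in 17 of 26 alternatives. It was 772 without the melanoma lines (802 with the same windows kept), 1322 with loops listed for at least 2 replicates, 3270 in 50 kb windows and 1039 in 250 kb windows. Leaving out each non-epithelial sample in turn, or renal cells, gave 1117 to 2601. Fewer samples or other numbers of windows tested enter these, and the cause was not tested further. Without renal cells, astrocytes and melanocytes, the samples with the lowest replicated shares, 2252 windows differed. Leaving out a sample took named windows below the filter, so 30 values of the epithelial and 25 of the supplier windows could not be tested there. With the same windows kept these were tested. The named windows had been chosen for large folds past the threshold in the same data. Their stability was favoured by that choice and is no separate support. In all, 272 of 274 values of the named epithelial windows and 215 of 215 of the supplier windows kept direction and call. The 2 that did not were chr2:145,200,001–145,300,000 without the melanoma lines (−4.93, limma adjusted p = 0.061 with either set of windows, and 0.0025 at first). Of 63 values of the named melanoma windows 37 moved by less than 1 log2 unit and 26 by more.

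Loop length passed the test in replicated lists of equal length (−18.9 kb), where leaving out each non-epithelial sample gave −24.7 to −5.91 kb. The call was lost without melanocytes (−5.91 kb) and without astrocytes, where the difference itself stayed near its size (−18.4 kb). In the full lists leaving out each non-epithelial sample gave −5.23 to −0.227 kb, with no call. The median share of loops in no other sample ran from 4.53% with anchors within 1 bin to 15.5%.

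Windows higher and lower in both melanoma lines, 5043 and 4108 at first, were 2717 and 4379 with equal list lengths, 3955 and 1794 with numbers of loops, 3010 and 2161 at a fold of at least 4, and 7305 and 2480 with replicated loops. Using 1 line gave 7217 to 7409 higher and 5285 to 5877 lower. The cause was not tested.

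Alternatives fixed before the data were examined for gene lists, marker genes and the count-model test were not run, since no hg19 annotation was used here and the value column was not a count. Unknown library depth limits every statement on listed zeros. No paired analysis was possible because the labels give each cell type 1 list and no replicate numbers.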

Other observations

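All values in this part were looked up after the data had been seen. Several windows high in 1 epithelial type were nearly as high in another cell type. Airway cells had 1381 CPM at chr6:150,500,001–150,600,000, where keratinocytes followed with 1037. Prostate cells had 324 at chr10:108,100,001–108,200,000, below the 410 of keratinocytes. Ovarian cells had 301 at chr20:47,000,001–47,100,000, followed by colon cells with 287. Pancreas cells had 381 at chr19:52,300,001–52,400,000, followed by esophageal cells with 377. A wider gap was seen in renal cells at chr13:37,700,001–37,800,000, with 599 and next 109 in astrocytes, in a list whose replicates differed.

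GM12878 was listed at 0 at chr3:111,500,001–111,600,000, where the median of the other 16 samples was 627 CPM, and at chr21:40,200,001–40,300,000, where it was 612. Melanocytes were listed at 0 at chr8:128,300,001–128,400,000, where the median of the others was 880. COLO 829 was listed at 0 at chr17:70,400,001–70,500,000, with a median of 611 over the others.

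Contacts were most concentrated in airway cells, where 1% of windows (249) held 27.4% of the contacts, and least in uterine cells, where they held 15.0%.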
